A study of Mus musculus with 12 samples.

How the data were processed

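The material was 12 RNA libraries of sorted mouse CD8 T cells, 3 for each of 4 treatments, sequenced on an Illumina HiSeq instrument per the labels. The labels' extraction text also speaks of cultured mouse embryonic fibroblasts, which does not match the sorted T cells of the other fields. Per the submitters' processing notes the reads were handled with TopHat2, bedtools and DESeq and with the builds mm10 and GRCm38, and no versions, order or roles were given. The deposited table held 1 read count per gene and library, as whole numbers written with commas between groups of 3 digits and not normalized, beside the exon length of each gene (median 2690 bases). All 12 sample columns were used, and each was matched to its library by treatment and replicate number in the file header.

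Commas were removed and the values summed per library. Totals ran from 29.3 M (mega) to 84.5 M reads. Of the values from 1 to 20, 55.6% to 64.4% were even in the different libraries, against 49.3% to 50.8% of the values over 1000, so read pairs may each have been counted as 2 and the totals need not equal numbers of fragments. The notes do not speak of duplicate reads being removed, and reads are not independent molecules, so floors given as a number of reads cover counting error only. Within groups the libraries correlated at 0.9609 to 0.9936 across genes. Gene symbols were matched to the RefSeq annotation of GRCm38.p6, which gave coordinates for 16313 of 16353 genes, and 1671 symbols differed from the current ones. The table also held 22 symbols in the form of dates, and these genes were placed through their transcript accession.

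Counts were scaled to CPM with trimmed mean of M factors (0.897 to 1.22), written in R from the published formula with 30.0% of M and 5% of A trimmed. Genes were kept with at least 0.258 CPM, which is 10 reads at the median library size, in 3 or more libraries and with at least 15 reads in all. This left 12499 genes, and 38 genes had 0 reads in every library. The test was limma-trend (limma 3.58.1, R 4.3.3) on log2(CPM + 1), with 4 group means and all 12 libraries in 1 fit, and Benjamini-Hochberg adjusted p under 0.05 over all tested genes in each of the 6 comparisons. The plan made before the files were opened named a negative binomial quasi-likelihood test for counts and limma-trend for other units. The values are read counts, but with their commas they read as text in the format check, so their unit was recorded as other and limma-trend was used. The negative binomial test was tried once outside this pipeline and its results are not given here. The test was tried on simulated reads with known changes before use.

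The 33 gene lists had been fixed before the table was opened and held 692 genes, of which 663 were in the table, 11 of them found through a gene identifier, and 628 were tested. Lists were tested with camera, 2-sided, at a preset correlation of 0.01 between genes, adjusted over all lists and comparisons. Members were counted as passing over all genes and, separately, with p-values adjusted over the list alone. Named genes followed a rule fixed beforehand. It took per comparison the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between libraries, without predicted genes and receptor or antibody segments, the 4 members of each list with the smallest adjusted p, and 30 reference genes of T cell biology. Genes named outside this rule, which are the genes given as examples of opposite direction, Rrm2 and Cdk1 in tolerized against activated cells, and the genes first named in the closing section, were chosen after their values were seen.

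The alternatives were median-of-ratios, upper-quartile (75.0% quantile) and library-size scaling, limma-voom, no filter, a filter at 5 CPM, pseudocounts of 0.1 and 5, only the 2 groups compared in the fit, a replicate block, each library left out in turn, and at least 2-fold change. For lists they were an estimated correlation, the fry test and the block. Alternatives added after the values were seen left out the libraries richest in naive or macrophage transcripts, or fitted the 9 antigen-exposed libraries with or without a covariate. Whether replicate numbers pair the libraries was checked by the correlation of their deviations from the group means, since the labels do not say what a number marks. All 3 same-number pairs correlated over 0.1 between tolerized and activated cells (0.19 to 0.60) and between inflamed and activated cells (0.15 to 0.64), and not all 3 did in the other 4 comparisons. A fit of these 2 comparisons with the pairs as a block, in the 2 groups alone, was added after the values were seen. The pairing comes from the data alone, and the unpaired fit was kept as planned. Some libraries correlated better with another number: activated 3 with inflamed 2 at 0.56 against 0.15 with inflamed 3. Activated 2 stood at 0.25 with inflamed 3 against 0.23 with inflamed 2, and at 0.21 with tolerized 3 against 0.19 with tolerized 2. Across all groups 6 of 12 libraries correlated best with their own number, so the numbers need not mark true pairs. No library was left out of the results given first. Some genes are not reported here. No raw reads were analysed here.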

Results

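Messenger RNA was sequenced from CD8 T cells of KB5 mice, whose transgenic T cell receptor recognises an antigen of C57BL/6 cells. The cells were sorted from spleens of CBA/J mice 12 h after treatment, to a purity of 95% by the labels, on the KB5 receptor and CD8. The 12 libraries fell into 4 groups of 3. Naive cells came from untreated mice. Activated cells came from mice given 10 M (mega, cells here and reads below) C57BL/6 splenocytes intravenously. Tolerized cells came from mice given the same splenocytes and 0.5 mg of anti-CD154, an antibody that blocks CD40 ligand and so withholds a costimulatory signal. Inflamed cells came from mice given splenocytes, anti-CD154 and 100 µg of lipopolysaccharide (LPS), a bacterial product that triggers inflammation.

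The reads assigned to genes numbered 39.4 M, 84.5 M and 31.3 M in the naive libraries and 30.3 M, 38.1 M and 53.1 M in the activated libraries. They numbered 29.3 M, 46.1 M and 35.5 M in the tolerized libraries and 35.8 M, 53.4 M and 43.6 M in the inflamed libraries. Of 16353 genes listed, 12499 had enough reads to be tested. Levels are given as counts per M reads (CPM) with the SD of 3 libraries, and changes as log2 fold changes ± SE from 3 libraries per group. Adjusted p-values are from limma over all 12499 genes. The labels call the libraries independent but do not say that they came from separate mice, so the p-values measure only the spread between these samples. The first principal component held 75.6% of the variance and parted the naive libraries from the other 9.

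**Figure D1:**
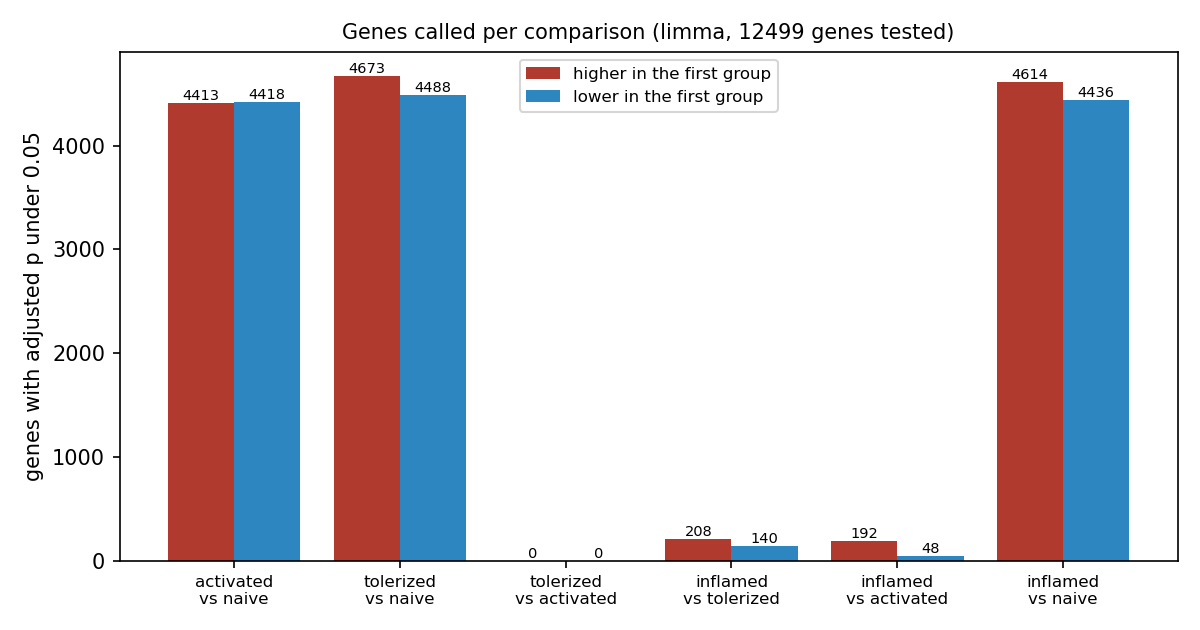
Number of genes (vertical axis) with a limma adjusted p under 0.05 in each of the 6 comparisons of 3 against 3 libraries, out of 12499 genes tested; red bars count genes higher and blue bars genes lower in the group named first. The counts run from 0 in tolerized against activated cells to 4673 higher genes in tolerized against naive cells.

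Activated against naive cells showed what donor splenocytes alone did by 12 h. Xcl1, a chemokine gene (GRCm38 chromosome 1, 164931644 to 164935522), rose from 0.933 ± 0.145 CPM in naive to 815 ± 325 CPM in activated cells, a log2 change of 8.65 ± 0.24 (adjusted p = 8.15e-09). The costimulatory receptor gene Tnfrsf9 (chromosome 4, 150920155 to 150946104) rose by 7.95 ± 0.19, from 1.83 ± 0.32 to 707 ± 155 CPM. Il2ra, which encodes the alpha chain of the IL-2 receptor (chromosome 2, 11642792 to 11693194), rose by 6.01 ± 0.23, Ifng by 5.83 ± 0.30 and the granzyme gene Gzmb by 5.03 ± 0.60. Il7r, the IL-7 receptor gene of resting T cells (chromosome 15, 9506159 to 9529941), fell by 3.27 ± 0.94 on the log2 scale, from 268 ± 20.8 to 42.8 ± 41.7 CPM (adjusted p = 0.0094).

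Several lists of growth and metabolism genes were higher in activated than in naive cells. All 32 measured genes of ribosome biogenesis rose, with a median log2 change of 2.77 (adjusted p = 2.8e-14), among them Srm (3.94 ± 0.18) and Nop16 (3.31 ± 0.17). In the glycolysis list 16 of 20 genes rose and 3 fell, with a median of 1.36 (adjusted p = 9.77e-05), including Pgam1 (3.13 ± 0.14) and Ldha, the lactate dehydrogenase gene (2.53 ± 0.14). For oxidative phosphorylation 24 of 28 genes rose and none fell (median 0.87, adjusted p = 5.48e-06), led by the cytochrome c gene Cycs at 2.57 ± 0.13. G1/S and DNA replication genes rose in 22 of 29 cases and fell in 2, with a median of 1.58 (adjusted p = 2.23e-05) and with the helicase genes Mcm5 (2.24 ± 0.10) and Mcm2 (2.47 ± 0.13) among them. Amino acid and one-carbon genes rose in 14 of 21 cases and fell in 1 (median 1.66, adjusted p = 0.000612), with Shmt1 at 4.26 ± 0.18. Endoplasmic reticulum chaperones rose in 15 of 20 cases and fell in 3 (median 1.14, adjusted p = 0.0111), with Canx at 1.88 ± 0.16. Sterol and fatty acid genes rose in 13 of 26 cases and fell in 3, or 2 when adjusted over the list alone (median 0.48, adjusted p = 0.023), with Idi1 at 2.61 ± 0.17. Adjusted over the list alone, the counts of the other 6 lists were identical. With an estimated correlation between genes these 7 calls were lost. Glycolysis then had adjusted p = 0.559 with an estimated correlation, sterol genes had adjusted p = 0.742 with an estimated correlation, and the remaining lists had adjusted p = 0.634 with an estimated correlation.

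Activation receptors rose in 20 of 27 cases and fell in 2 (median 2.30, adjusted p = 7.03e-05, adjusted p = 0.634 with an estimated correlation), and adjusted over the list alone the counts were identical. Nr4a3, a nuclear receptor gene induced through the T cell receptor, rose by 5.85 ± 0.24, Irf4 by 5.17 ± 0.36 and Myc by 3.53 ± 0.25, while Cd44 stood at -0.25 ± 0.42 and Icos at 0.04 ± 0.23 (adjusted p = 0.617 and 0.892). Effector genes rose in 13 of 26 cases and fell in 6, as also when adjusted over the list alone, and the list as a whole was not called (median 0.83, adjusted p = 0.0794). Its call was gained without naive replicate 3 or activated replicate 2, with a lowest adjusted p of 0.0449 over the leave-one-out fits. Within it the transcription factor gene Eomes rose by 5.78 ± 0.22 and Fasl, which encodes a death ligand, by 5.08 ± 0.30. Co-inhibitory receptors went both ways, with 7 of 18 rising and 7 falling (adjusted p = 0.733, counts identical when adjusted over the list alone). Lag3 rose by 5.68 ± 0.22 and Pdcd1, the PD-1 gene, by 5.14 ± 0.24, and Ctla4 stood at -0.09 ± 0.71 (adjusted p = 0.917).

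Genes of resting T cells and of interferon responses were lower in activated than in naive cells. Naive and quiescence genes fell in 23 of 26 cases and rose in 3, with a median of -1.66 (adjusted p = 0.000498), Btg1 among them at -1.53 ± 0.19 and Satb1 at -1.23 ± 0.20. Type I interferon-stimulated genes fell in 34 of 40 cases, or 35 when adjusted over the list alone, and none rose (median -1.68, adjusted p = 2.23e-05). Irf7 fell by 2.42 ± 0.60 on the log2 scale. Interferon gamma and antigen presentation genes fell in 24 of 30 cases and rose in 2 (median -1.59, adjusted p = 3.87e-05), with the class I gene H2-K1 at -0.91 ± 0.12. The interferon-stimulated list had adjusted p = 0.706 with an estimated correlation, and the other 2 lists had adjusted p = 0.634 with an estimated correlation. T cell identity genes fell in 11 of 14 cases and rose in 2 (median -0.73, adjusted p = 0.0191), with Cd8a at -0.53 ± 0.14. Chemokine receptor and adhesion genes fell in 15 of 24 cases and rose in 1 (median -1.14, adjusted p = 0.0143), with the integrin gene Itgae at -3.15 ± 0.58. Both of these had adjusted p = 0.634 with an estimated correlation, and adjusted over the list alone no count of these lists differed except the one given.

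Markers of other spleen cells were lower in activated than in naive libraries as well. All 16 B cell markers fell (median -1.86, adjusted p = 7.7e-06), including Cd79b from 60.6 ± 5.2 to 15.8 ± 0.837 CPM. Erythroid markers fell in 14 of 15 cases and rose in 1 (median -2.62, adjusted p = 0.000612), and the gene that rose was Tfrc, the transferrin receptor gene that growing cells also use. The haemoglobin genes Hbb-b1 and Hbb-b2, near-identical copies whose reads cannot be assigned uniquely, had the largest falls of genes above 10 CPM, at -3.59 ± 0.82 each. Dendritic cell markers fell in 10 of 14 cases (median -1.07, adjusted p = 0.00487) and NK cell markers in 6 of 9 (median -0.91, adjusted p = 0.017). All 4 platelet markers fell (median -1.34, adjusted p = 0.0407). Each of these 5 lists had adjusted p = 0.634 with an estimated correlation. Monocyte and macrophage markers fell in 11 of 19 cases (median -2.31, adjusted p = 0.00779, adjusted p = 0.795 with an estimated correlation), and without activated replicate 3 the list had an adjusted p of 0.0522. Its median ran from -3.15 to -1.79 over the leave-one-out fits. The list's mean log2(CPM + 1) was 4.96, 3.21 and 2.26 in activated replicates 1, 2 and 3. In naive replicates 1, 2 and 3 it was 4.99, 6.04 and 6.12, so activated replicate 1 stood near naive replicate 1. Adjusted over the list alone, the counts of these 6 lists were identical.

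In this comparison 4413 genes were higher and 4418 lower in activated cells by limma, 8831 of 12499 or 70.7%. Scaling by library size alone moved the median change of all genes by -0.22 here, -0.24 in tolerized and -0.27 in inflamed against naive cells, and the upper-quartile factor moved it by -0.16, -0.18 and -0.17. With library size alone 39.1% of the called genes were higher in activated cells, so the balance of higher and lower genes depends on the scale. All scales used are relative, so rises and falls in all comparisons are relative to the other genes of a library. Amounts of RNA per cell were not measured. Of the 8831 calls 8010 were made in the same direction with library size alone and 0 in the opposite one.

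Over all 6 comparisons 87 list tests were called with the preset correlation, and 0 of them with an estimated correlation, so list calls rest on that preset. Of the named genes called in activated against naive cells, 149 of 157 kept their call in every fit that left out a library, as did 147 of 153 in tolerized and 146 of 153 in inflamed against naive cells. Against tolerized cells 36 of 63 named calls of inflamed cells were kept so, and against activated cells 33 of 53.

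Tolerized against naive cells asked what the same splenocytes did under costimulation blockade. The genes with the largest rises were again Xcl1, at 8.84 ± 0.24 (898 ± 224 CPM), and Tnfrsf9, at 8.02 ± 0.19. Lag3 rose by 6.33 ± 0.22, to 310.0 ± 5.56 CPM, Ifng by 5.99 ± 0.30 and Il2ra by 6.08 ± 0.23. Among the genes that fell were Dntt, at -5.17 ± 0.75, Il7r, at -4.88 ± 0.94, Itgae, at -4.78 ± 0.58, and the transporter gene Slc16a5, at -4.84 ± 0.87. Ribosome biogenesis genes rose in 32 of 32 cases (median 2.81, adjusted p = 2.22e-13) and G1/S genes in 24 of 29 with none falling (median 1.90, adjusted p = 2.44e-07), each with adjusted p = 0.634 with an estimated correlation. Glycolysis genes rose in 16 of 20 cases and fell in 3 (median 1.51, adjusted p = 6.4e-05, adjusted p = 0.559 with an estimated correlation). Naive and quiescence genes fell in 22 of 26 cases and rose in 3 (median -1.83, adjusted p = 0.000217). Interferon gamma and antigen presentation genes fell in 27 of 30 and rose in 1, or 2 when adjusted over the list alone (median -1.83, adjusted p = 3.59e-06). Both lists had adjusted p = 0.634 with an estimated correlation. Type I interferon-stimulated genes fell in 31 of 40 cases and none rose (median -1.71, adjusted p = 2.24e-05, adjusted p = 0.706 with an estimated correlation). B cell markers fell in 16 of 16 cases (median -1.75, adjusted p = 1.85e-05, adjusted p = 0.634 with an estimated correlation), and macrophage markers in 17 of 19 (median -3.03, adjusted p = 0.00159, adjusted p = 0.72 with an estimated correlation). Adjusted over the list alone, the remaining counts of this paragraph were identical.

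G2/M genes were uneven among the tolerized libraries. Against naive cells 14 of 25 rose and 1 fell, or 12 and 1 when adjusted over the list alone, and the list itself was not called (median 1.56, adjusted p = 0.0518). It was called without naive replicate 3, activated replicate 2 or tolerized replicate 1, over a range of adjusted p from 0.000445 to 0.223, and its median was 0.85 without tolerized replicate 3. Anergy and deletional tolerance genes rose in 10 of 23 cases and fell in 5, with the same counts when adjusted over the list alone (adjusted p = 0.337). In all 4673 genes were higher and 4488 lower in tolerized than in naive cells, 73.3% of those tested. With library size alone 39.6% of the called genes were higher in place of 51.0%.

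**Figure D2:**
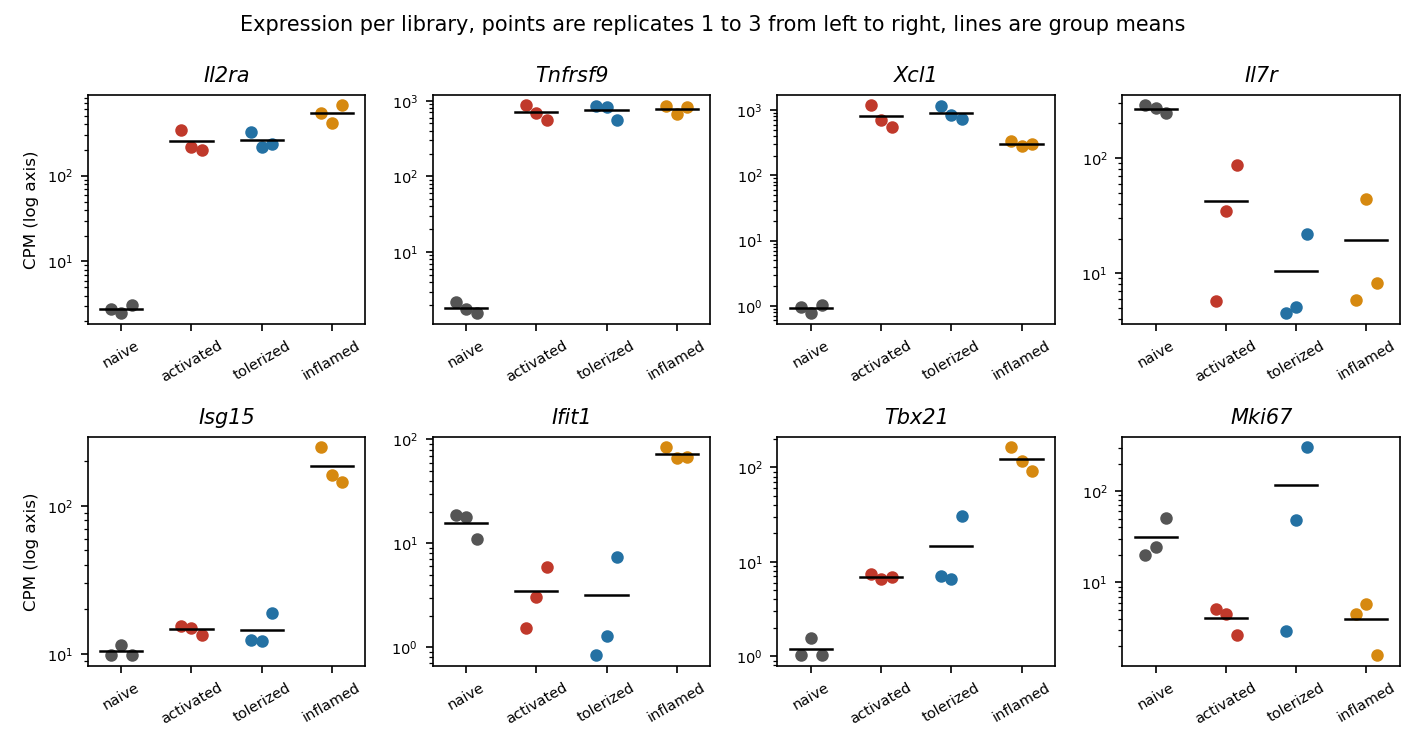
Normalised level in CPM (vertical log axes, each panel with its own scale) of 8 genes in the 12 libraries; points are replicates 1 to 3 of each group and lines are group means. Il2ra, Tnfrsf9 and Xcl1 were under 4 CPM in naive cells and above 190 CPM in all 9 antigen-exposed libraries, Isg15 and Tbx21 stood highest in inflamed cells, and Mki67 reached 301 CPM in tolerized replicate 3.

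Tolerized against activated cells asked what costimulation blockade changed in cells that had met the same antigen. Their activation genes stood at like levels: Tnfrsf9 differed by 0.07 ± 0.19 on the log2 scale, Il2ra by 0.07 ± 0.23, Ifng by 0.16 ± 0.30, Myc by 0.03 ± 0.25 and Irf4 by 0.11 ± 0.36. Lag3 stood at 310.0 ± 5.56 CPM in tolerized and 200.1 ± 41.0 CPM in activated cells, a log2 difference of 0.65 ± 0.22 that did not pass (adjusted p = 1). No gene passed with limma (smallest adjusted p = 0.957), against 531 genes at an unadjusted p under 0.05, and 0 passed with limma-voom. With these 2 groups alone and the replicate numbers as pairs 0 genes passed as well (limma, smallest adjusted p = 0.605), against 907 at an unadjusted p under 0.05. The median 95% interval reached 0.342 to either side, and for 10869 genes, 87.0%, the whole interval lay within 2-fold. These intervals rest on the spread of all 12 libraries, and without the naive ones the median interval reached 0.373. In simulated reads with 3 libraries per group the test found 28.0% of genes changed 1.5-fold and 80.0% of genes changed 4-fold, so many smaller differences were not detectable.

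Cell cycle genes as lists were higher in tolerized than in activated cells. G1/S and DNA replication genes had a median log2 difference of 0.44 (adjusted p = 9.97e-27), with 0 of 29 genes passing over all genes and 20 when adjusted over the list alone. Mcm3 stood at 287 ± 23.8 against 209 ± 26.0 CPM and Mcm7 at 213 ± 8.81 against 158 ± 20.3 CPM. This list had adjusted p = 0.257 with an estimated correlation. G2/M genes had a median of 1.68 (adjusted p = 1.35e-24, adjusted p = 0.559 with an estimated correlation), again with 0 of 25 genes passing over all genes and 20 when adjusted over the list alone. Their spread lay between libraries: Mki67, a marker of cycling cells (chromosome 7, 135689784 to 135716450), stood at 2.96, 48.5 and 301 CPM in the tolerized libraries and at 5.11, 4.56 and 2.68 CPM in the activated ones. Without tolerized replicate 1, 60 genes passed, 59 higher and 1 lower in tolerized cells, and 11 of them were on the G1/S or G2/M lists, among them Mki67, Rrm2 and Cdk1. Both list calls held in each of the 12 fits that left out a library, but the G2/M median was 0.86 without tolerized replicate 3.

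Other list differences between tolerized and activated cells were smaller. Glycolysis genes were higher by a median of 0.16 (adjusted p = 2.63e-06, adjusted p = 0.426 with an estimated correlation), with 0 of 20 genes passing and 1 when adjusted over the list alone. The median was 0.24 without activated replicate 1, 0.03 without activated replicate 3 and 0.10 without tolerized replicate 1. Interferon gamma and antigen presentation genes were lower, with a median of -0.40 (adjusted p = 9.37e-10, adjusted p = 0.634 with an estimated correlation) and none of 30 passing either way. Their median was -0.11 without activated replicate 3, -0.18 without tolerized replicate 1 and -0.62 without tolerized replicate 3. Naive genes had a median of -0.23 (adjusted p = 0.00256, adjusted p = 0.673 with an estimated correlation), with a highest adjusted p of 0.833 and the call lost without activated replicate 3, tolerized replicate 1 or tolerized replicate 2. Their median turned to 0.02 without activated replicate 3, and was -0.09 without tolerized replicate 1, -0.50 without tolerized replicate 3 and -0.58 without activated replicate 1. Macrophage markers had a median of -0.73 (adjusted p = 0.000638, adjusted p = 0.706 with an estimated correlation), and without activated replicate 1 the adjusted p was 0.865 and the median -0.05, while without activated replicate 3 the median was -1.40. The anergy list had a median of 0.11 (adjusted p = 0.0377, adjusted p = 0.634 with an estimated correlation) and the stromal list a median of -0.29 (adjusted p = 0.00869, adjusted p = 0.634 with an estimated correlation). The anergy call was lost without activated replicate 1, tolerized replicate 2, tolerized replicate 3 or inflamed replicate 1 (highest adjusted p 0.626), and its median was 0.02, 0.05 and 0.04 without activated replicate 1, activated replicate 2 and tolerized replicate 2. The stromal call was lost without activated replicate 1, activated replicate 3, tolerized replicate 2 or tolerized replicate 3 (highest adjusted p 0.686), and its median was -0.68, -0.01 and -0.76 without activated replicate 2, activated replicate 3 and tolerized replicate 1. No member of these last 4 lists passed, over all genes or adjusted over the list alone. Type I interferon-stimulated genes were not called (median -0.13, adjusted p = 0.157). Without activated replicate 1 or tolerized replicate 3 the list was called lower, with medians of -0.35 and -0.58 (lowest adjusted p 2.99e-14), and without activated replicate 3, tolerized replicate 1 or tolerized replicate 2 the median turned to 0.12, 0.16 and 0.04. With the replicate numbers as pairs the anergy and stromal calls were lost (adjusted p = 0.127 and 0.0624), and heat shock genes (adjusted p = 0.000107, adjusted p = 0.706 with an estimated correlation), type I interferon-stimulated genes (adjusted p = 0.00968, adjusted p = 0.889 with an estimated correlation) and NF-kB response genes (adjusted p = 0.0197, adjusted p = 0.706 with an estimated correlation) were called lower in tolerized cells.

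**Figure D3:**
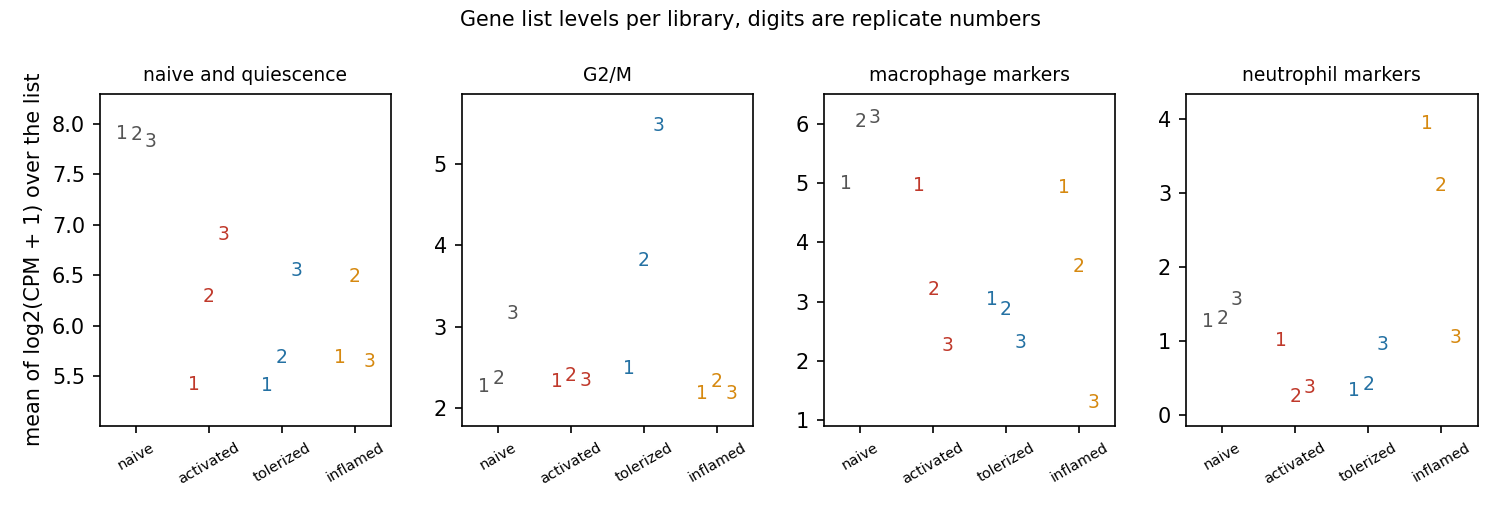
Mean log2(CPM + 1) of the members of 4 gene lists (vertical axes, each panel with its own scale) in each library; digits are replicate numbers within naive, activated, tolerized and inflamed cells. The G2/M mean was 2.49, 3.82 and 5.47 in the tolerized libraries against 2.33 to 2.40 in the activated ones, and the neutrophil mean was 3.94, 3.10 and 1.05 in the inflamed libraries.

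Inflamed against tolerized cells asked what LPS added to antigen and blockade. Interferon-stimulated genes rose together. Ifit1, an antiviral gene (chromosome 19, 34640889 to 34650009), rose by 4.49 ± 0.52, from 3.17 ± 3.67 to 72.7 ± 9.73 CPM (adjusted p = 0.00117), and Isg15, which encodes a ubiquitin-like modifier (chromosome 4, 156199424 to 156200818), rose by 3.57 ± 0.21, to 184 ± 55.5 CPM (adjusted p = 2.11e-05). Of the 40 type I interferon-stimulated genes 26 rose, or 35 when adjusted over the list alone, and none fell (median 2.34, adjusted p = 1.01e-42, adjusted p = 0.426 with an estimated correlation). Usp18 rose by 4.13 ± 0.58, Oasl1 by 3.56 ± 0.29 and Ifi35 by 1.46 ± 0.15. Interferon gamma and antigen presentation genes rose in 10 of 30 cases, or 17 when adjusted over the list alone (median 0.93, adjusted p = 6.01e-18, adjusted p = 0.559 with an estimated correlation), with the GTPase gene Irgm1 at 2.48 ± 0.22 and Socs1, a feedback inhibitor of cytokine signalling, at 2.20 ± 0.15.

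Cytokine and effector genes moved in both directions. Tbx21, which encodes the transcription factor T-bet (chromosome 11, 97098007 to 97115331), rose by 3.28 ± 0.45, from 14.8 ± 13.8 to 124 ± 35.7 CPM (adjusted p = 0.00289). Il10 (chromosome 1, 131019845 to 131024970) rose by 3.59 ± 0.17, from 0.180 ± 0.274 to 13.1 ± 1.54 CPM (adjusted p = 5e-06), Lif by 3.49 ± 0.32 and Maf, a transcription factor gene, by 3.94 ± 0.35. Il21 had 0 reads in every tolerized library and 4.01 ± 1.33 CPM in inflamed cells, at least 35.1-fold higher against the floor of 3 reads in a tolerized library. That bound is a ratio of CPM without the added 1, so it is not on the scale of the log2 changes given for Il10 and other genes. Fasl fell by 2.62 ± 0.30 on the log2 scale, from 59.2 ± 15.6 to 9.03 ± 3.86 CPM (adjusted p = 0.00101). The effector list as a whole, with 5 of 26 genes rising and 3 falling, or 9 and 5 when adjusted over the list alone, had a median of 0.54, which stayed at 0.54 with Il21 at its bound (adjusted p = 0.00762, adjusted p = 0.634 with an estimated correlation). Its call was lost without inflamed replicate 1, at an adjusted p of 0.187. Gzmb stood at 388 ± 57.7 against 111 ± 129 CPM (2.43 ± 0.60, adjusted p = 0.0644), and it passed without tolerized replicate 3, at an adjusted p of 1e-04. IL-2 and STAT5 response genes rose in 7 of 23 cases and fell in 1, or 11 and 2 when adjusted over the list alone (median 0.54, adjusted p = 4.96e-07, adjusted p = 0.222 with an estimated correlation). Among them the IL-12 receptor genes Il12rb1 and Il12rb2 rose by 1.86 ± 0.11 and 1.80 ± 0.15, and Stat3 by 0.85 ± 0.10. Of other genes, the cell cycle inhibitor gene Cdkn1a rose by 2.45 ± 0.39, and Bcl2l1, a survival gene, fell by 1.46 ± 0.23, Traf1 by 1.07 ± 0.13 and Cd226 by 0.93 ± 0.13 on the log2 scale. Wnt10b, at -2.51 ± 0.32, and the phosphatase gene Dusp4, at -2.20 ± 0.29, also fell.

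Cell cycle genes were lower in inflamed than in tolerized cells. G1/S and DNA replication genes fell in 9 of 29 cases, or 23 when adjusted over the list alone, and none rose (median -0.69, adjusted p = 1.49e-17, adjusted p = 0.426 with an estimated correlation), with Mcm3 at -0.79 ± 0.10 and Mcm7 at -0.72 ± 0.09. Of the 25 G2/M genes 0 passed over all genes and 23 were lower when adjusted over the list alone (median -1.61, adjusted p = 7.29e-14, adjusted p = 0.634 with an estimated correlation). Their median was -2.52 without tolerized replicate 1 and -0.83 without tolerized replicate 3, and the list mean of tolerized replicate 1 was 2.49, against 2.18 to 2.32 in the inflamed libraries. Amino acid genes rose in 1 of 21 cases, or 6 when adjusted over the list alone (median 0.26, adjusted p = 2.42e-05, adjusted p = 0.634 with an estimated correlation). The gene that passed was Psat1, a serine synthesis gene, at 0.57 ± 0.10, and without tolerized replicate 2 its adjusted p was 0.0545.

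Transcripts of other cells also differed in the inflamed libraries. Neutrophil markers had a median of 1.74 (adjusted p = 2.21e-09, adjusted p = 0.634 with an estimated correlation), with 1 of 11 genes rising, or 10 when adjusted over the list alone, and a median of 2.63 without inflamed replicate 3. That gene, Lcn2, stood at 41.4 ± 46.2 CPM in inflamed and 0.347 ± 0.319 CPM in tolerized cells (adjusted p = 0.0314), and its call was lost in 9 of the 12 fits that left out a library, with an adjusted p of 0.127 without inflamed replicate 2. S100a9 reached 122.5, 48.8 and 6.3 CPM in inflamed replicates 1, 2 and 3. Macrophage markers had a median of 0.58 and were not called (adjusted p = 0.117), though the list was called without inflamed replicate 3 (adjusted p = 6.61e-06). Their median was 1.52 without inflamed replicate 3, 0.32 without inflamed replicate 2, 0.16 without tolerized replicate 3 and -0.14 without inflamed replicate 1. Of the 14 genes of the dendritic list Bst2 rose, or 4 when adjusted over the list alone, and Bst2 is also on the type I interferon list. The dendritic list had an adjusted p of 0.0467 (adjusted p = 0.72 with an estimated correlation). It lost its call without activated replicate 1, activated replicate 3, tolerized replicate 1, inflamed replicate 1 or inflamed replicate 2 (highest adjusted p 0.189). The stromal list had 0 of 10 genes passing either way and a median of 0.63 (adjusted p = 0.00651, adjusted p = 0.634 with an estimated correlation), and without inflamed replicate 2 its adjusted p was 0.0512.

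In all 208 genes were higher and 140 lower in inflamed than in tolerized cells. The total of 348 fell to 157 without tolerized replicate 2, 179 without inflamed replicate 1 and 174 without inflamed replicate 2, and reached 540 without tolerized replicate 1. It was 158 with only these 2 groups in the fit, 203 without activated replicate 3, tolerized replicate 3 and inflamed replicate 2, the library of each antigen-exposed group richest in naive transcripts, and 217 without activated replicate 1 and inflamed replicate 1, the antigen-exposed libraries richest in macrophage transcripts.

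**Figure D4:**
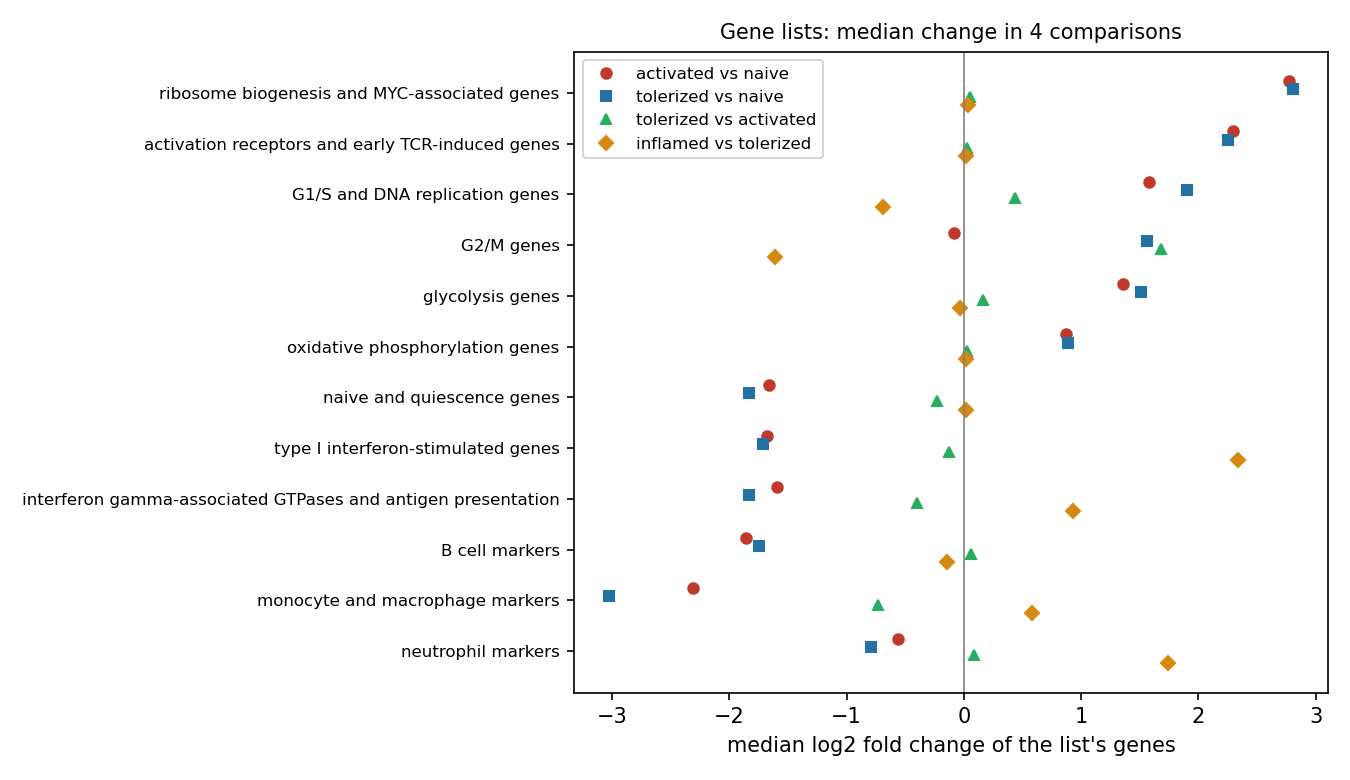
Median log2 fold change (horizontal axis) of the tested members of 12 gene lists in 4 comparisons of 3 against 3 libraries; circles show activated against naive, squares tolerized against naive, triangles tolerized against activated and diamonds inflamed against tolerized cells. The median of type I interferon-stimulated genes was -1.68, -1.71, -0.13 and 2.34 in these 4 comparisons, the third of which changed sign with single libraries left out.

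Inflamed against activated cells set antigen with blockade and LPS against antigen alone. Tbx21 rose by 3.94 ± 0.45, from 6.93 ± 0.41 to 124 ± 35.7 CPM (adjusted p = 0.00139), Il10 by 3.77 ± 0.17 and Lif by 3.69 ± 0.32. Tigit, a co-inhibitory receptor gene, rose by 2.43 ± 0.33. Ctla4, another such gene, rose by 4.07 ± 0.71 (adjusted p = 0.0138), but without inflamed replicate 2 or activated replicate 2 its adjusted p was 0.0631 and 0.06. Type I interferon-stimulated genes rose in 25 of 40 cases, or 35 when adjusted over the list alone, and none fell (median 2.50, adjusted p = 1.98e-47, adjusted p = 0.426 with an estimated correlation), with Isg15 at 3.53 ± 0.21. Interferon gamma and antigen presentation genes rose in 3 of 30 cases, or 8 when adjusted over the list alone (median 0.47, adjusted p = 1.93e-10, adjusted p = 0.634 with an estimated correlation), with Irgm1 at 2.03 ± 0.22. IL-2 and STAT5 response genes rose in 6 of 23 cases and none fell, or 8 and 3 when adjusted over the list alone (median 0.45, adjusted p = 6.09e-06, adjusted p = 0.222 with an estimated correlation), with Il12rb2 at 1.88 ± 0.15. Fasl fell by 2.17 ± 0.30 on the log2 scale, Wnt10b by 2.32 ± 0.32, the adapter gene Stap1 by 1.97 ± 0.23 and the adenosine receptor gene Adora2a by 1.63 ± 0.17.

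Smaller sets also differed between inflamed and activated cells. Amino acid genes rose in 1 of 21 cases, or 9 when adjusted over the list alone (median 0.35, adjusted p = 1.03e-06, adjusted p = 0.634 with an estimated correlation), with Psat1 at 0.75 ± 0.10 and a median of 0.22 without activated replicate 3. Glycolysis genes rose in 3 of 20 cases, or 6 when adjusted over the list alone (median 0.15, adjusted p = 0.000148, adjusted p = 0.559 with an estimated correlation), with Pfkp at 0.50 ± 0.07 and a median of 0.09 without activated replicate 3 or inflamed replicate 1. Effector genes rose in 6 of 26 cases and fell in 2, or 6 and 4 when adjusted over the list alone (median 0.40, adjusted p = 0.00727, adjusted p = 0.634 with an estimated correlation), and without inflamed replicate 1 the list had an adjusted p of 0.128. Its median was 0.23 without inflamed replicate 1 or activated replicate 2. Neutrophil markers rose in 2 of 11 cases, or 11 when adjusted over the list alone (median 1.98, adjusted p = 6.93e-11, adjusted p = 0.634 with an estimated correlation). G1/S genes had 0 of 29 passing either way (median -0.14, adjusted p = 0.00714, adjusted p = 0.669 with an estimated correlation), and the call was lost without activated replicate 1 or activated replicate 2 (highest adjusted p 0.155), with a median of -0.22 without activated replicate 3. In all 192 genes were higher and 48 lower in inflamed than in activated cells. The total of 240 fell to 107 without activated replicate 2, 125 without inflamed replicate 1 and 121 without inflamed replicate 2, to 101 with only these 2 groups in the fit, to 147 without the library of each antigen-exposed group richest in naive transcripts and to 103 without the 2 antigen-exposed libraries richest in macrophage transcripts. With these 2 groups alone and the replicate numbers as pairs 68 genes passed, 61 higher and 7 lower. Tbx21, Il10, Lif, Tigit, Ctla4, Isg15 and Il12rb2 were among those that passed, and Fasl (adjusted p = 0.117), Wnt10b (0.07), Stap1 (0.07), Adora2a (0.0568), Irgm1 (0.065), Psat1 (0.114) and Pfkp (0.127) did not.

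Inflamed against naive cells set the full treatment against none. Gzmb rose by 8.06 ± 0.60, from 0.462 ± 0.262 to 388 ± 57.7 CPM (adjusted p = 9.15e-07), the chemokine gene Ccl4 by 8.17 ± 0.44 and Lif by 7.48 ± 0.32. Effector genes rose in 16 of 26 cases and fell in 5, as also when adjusted over the list alone (median 2.21, adjusted p = 0.00826, adjusted p = 0.634 with an estimated correlation). Ribosome biogenesis genes rose in 32 of 32 cases either way (median 2.83, adjusted p = 1.3e-13, adjusted p = 0.634 with an estimated correlation). Type I interferon-stimulated genes rose in 19 of 40 cases and fell in 1, or 14 and 1 when adjusted over the list alone, and the list was not called (median 0.99, adjusted p = 0.173). Isg15 rose by 3.99 ± 0.21 and Irf7 stood at 0.81 ± 0.60 (adjusted p = 0.245). The interferon gamma and antigen presentation list fell in 16 of 30 cases and rose in 4 either way (median -0.84, adjusted p = 0.0413, adjusted p = 0.854 with an estimated correlation), and the call was lost without naive replicate 1 or inflamed replicate 3 (highest adjusted p 0.12). The iron exporter gene Slc40a1 (chromosome 1, 45908070 to 45926532), at -5.64 ± 0.98, and the macrophage receptor genes Mrc1 and Cd163, at -5.56 ± 0.84 and -5.00 ± 0.71, had some of the largest falls. Macrophage markers as a list fell in 12 of 19 cases either way (median -2.47, adjusted p = 0.00899, adjusted p = 0.795 with an estimated correlation), with a median of -1.60 without inflamed replicate 3. In all 4614 genes were higher and 4436 lower. With library size alone 38.6% of the called genes were higher in place of 51.0%.

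Changes against naive cells were largely shared. Of the 8831 genes called in activated against naive cells, 8436 were also called in tolerized against naive cells in the same direction, 4302 higher and 4134 lower, and 0 in the opposite direction. Independent calls would share 1650 and 1586. The log2 changes of the 2 comparisons correlated across genes at r = 0.979, and genes are not independent replicates. The mean was 0.495 in 20 simulations that redrew all 12 libraries, naive ones included, without differences between groups. Tolerized and inflamed cells shared 4203 higher and 3941 lower genes against naive cells (r = 0.94 across genes, 0.495 in simulation), and 38 genes went in opposite directions. Of these, 31 were lower in tolerized and higher in inflamed than in naive cells, such as Ifit1 (-2.32 and 2.16), Maf (-2.28 and 1.65) and Oasl1 (-1.23 and 2.33), and 7 the reverse, such as Id3, an inhibitor of E proteins (0.99 and -0.35).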

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

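The tests of read depth, of mixed-in naive cells, of RNA carried over from other cells and of splits by pairs were chosen only after the results were seen, and those of all library splits and of the naive covariate were written down before. Set apart for a direction that differed between treatments were 31 genes lower than naive in tolerized and higher than naive in inflamed cells, and 7 genes the other way. All had a passing difference between inflamed and tolerized cells. That follows from the choice and adds no support. Both comparisons use the same naive libraries and the same SE, so opposite calls add up to a large difference. Among the 31 were Ifit3 (-2.66 and 1.58), Usp18 (-1.85 and 2.28), Rsad2 (-2.32 and 1.24) and Socs1 (-1.16 and 1.05), and among the 7 were Plcl1 (0.94 and -0.39), Zhx2 (0.42 and -0.55) and Hdac7 (0.48 and -0.36). Their number depended on the libraries and the scaling, from 21 without naive replicate 2 to 49 without inflamed replicate 3 for both directions together.

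For each comparison the 6 libraries were also split into 3 and 3 in all 10 ways. The real split of activated against naive cells was the only 1 of 10 with as many calls, and the highest other split gave 3. The same held for tolerized against naive (1 split, highest other 0), inflamed against tolerized (1, highest other 0), inflamed against activated (1, highest other 42) and inflamed against naive cells (1, highest other 1). For tolerized against activated cells the real count was 0, so that all 10 splits had to reach it and their number says nothing, and the highest other gave 1234. That split set activated 1, tolerized 1 and tolerized 2 against activated 2, activated 3 and tolerized 3. So the libraries of the 2 treatments differed along a line that was not the treatment. It parted the 3 libraries poorest in naive T cell transcripts, at 3.36% to 8.24% of the naive level (defined below), from the 3 richest, at 15.8% to 31.4%. It kept the libraries numbered 1 together and those numbered 3 together, and the 4 splits that part all 3 same-number pairs, the real one included, each gave 0. For inflamed against activated cells the other splits that part all 3 pairs gave 0, and the split with 42 kept pairs 1 and 2 together. That split likewise set the 3 libraries poorest in naive transcripts, at 3.96% to 4.59%, against the 3 richest, at 15.8% to 31.4%. Replicate number and naive transcripts were not tested apart by these splits. With 10 splits no share can fall under 0.05.

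Naive T cell transcripts differed between libraries of one treatment: 3.96%, 15.8% and 31.4% of the naive level in activated replicates 1, 2 and 3, 3.36%, 8.24% and 23.8% in tolerized replicates and 4.59%, 16.4% and 3.99% in inflamed replicates. These are medians of 124 naive-high genes chosen from these data for a very low level in an antigen-exposed library. The low percentages thus follow in part from the choice, and the preset naive list fell less (median -1.66 in activated against naive cells). Il7r was among the genes that varied so. If cells that had not met antigen were mixed in, induced genes should have been diluted in the richest library of each group. The 29 induced genes were also chosen from these data, for a very low naive level. Their observed over predicted level was 0.869 in the median group. It was 0.766 in activated (interval 0.686 to 0.821), 0.869 in tolerized (0.792 to 0.956) and 1 in inflamed cells (0.895 to 1.08). The intervals come from resampling these genes within a single pair of libraries per group, and do not measure the spread between libraries. The result stayed undecided, and a share of unresponsive cells or a slower loss of naive transcripts might each give such values. The richest library had the highest total in 2 of 3 groups, but the mean of the naive list ranged over 0.09 log2 units in the naive libraries, whose totals differed 2.7-fold, against 0.84 to 1.48 within the antigen-exposed groups with totals 1.49-fold to 1.75-fold apart, which argues against depth as the whole cause.

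That no gene passed between tolerized and activated cells could have come from this spread hiding differences. With the naive list mean as a covariate among the 9 antigen-exposed libraries 0 genes passed, where at least 10 had been set as the mark beforehand, and the smallest adjusted p was 0.333. Genes at an unadjusted p under 0.05 went from 389 to 1187, and the median interval narrowed from 0.373 to 0.293 on either side. The mark was not met. But the same covariate raised the calls from 195 to 802 in inflamed against tolerized and from 144 to 413 in inflamed against activated cells. With many smaller differences not detectable, a count of 0 cannot decide whether this spread hid differences between tolerized and activated cells. G2/M transcripts such as Mki67, at 2.96 to 301 CPM in the tolerized libraries, remain a second source of spread.

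The rise of interferon-stimulated genes in inflamed over tolerized cells might have been RNA of other cells. Macrophage markers were higher by a median of 0.58, with an SE of 0.21 taken over the 19 genes and not over libraries. The median rise of the 26 called interferon-stimulated genes was 2.83. But the macrophage median was 1.52 without inflamed replicate 3, 0.32 without inflamed replicate 2, 0.16 without tolerized replicate 3 and -0.14 without inflamed replicate 1. So this test decides nothing. Across the 3 inflamed libraries the level of 16 macrophage genes ranged over 5.28 log2 units in the median and that of the interferon-stimulated genes over 0.91. Without inflamed replicate 3 the ranges were 1.62 and 0.50, which argues against macrophage RNA as the whole cause. But the order was shared. In inflamed replicates 1, 2 and 3 the mean log2(CPM + 1) of the whole interferon list was 6.06, 5.64 and 5.11. It was 4.93, 3.59 and 1.30 for the macrophage list and 3.94, 3.10 and 1.05 for the neutrophil list. A part from other cells thus stays open. The excess of the interferon-stimulated genes over tolerized cells ranged over 1.08 (upper quartile 1.46) and that of 6 neutrophil genes over 5.15, but without inflamed replicate 3 over 0.60 and 1.23, so neutrophil RNA stays open. RNA of other cells, dendritic cells among them, and a response of the T cells themselves were not tested.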

How the results depend on the processing

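Asking for at least 2-fold change left 4332 genes in activated, 4714 in tolerized and 4651 in inflamed against naive cells, 174 in inflamed against tolerized and 123 in inflamed against activated cells, 4154 and 4052 genes in the shared-direction counts, and 13 of opposite direction, by construction. With only the 2 groups in the fit 158 (inflamed against tolerized) and 101 (inflamed against activated) passed. Settings chosen after seeing the data gave, in the same order, 203 and 147 without the libraries richest in naive transcripts, 217 and 103 without those richest in macrophage transcripts, 195 and 144 with the 9 antigen-exposed libraries, and 802 and 413 when these had the naive list mean as covariate. The pairs as a block in the 2 groups alone, also chosen so, gave 68 in inflamed against activated and 0 in tolerized against activated cells. In the lists of these comparisons it also ended the gamma delta T call (adjusted p 0.129) and added the dendritic one (0.0411, 0.706 with an estimated correlation) in inflamed against activated cells, and beside the list calls given with the results it changed no other. Library size alone left 21 genes of opposite direction. Of 87 list calls 0 held with an estimated correlation, and fry gave 104. Leaving out 1 library gave 7840 to 8932 genes in activated, 8267 to 9296 in tolerized and 8148 to 9204 in inflamed against naive cells. It gave 0 to 60 in tolerized against activated cells, the 60 without tolerized 1 and 0 without any other library. It gave 157 (without tolerized 2) to 540 (without tolerized 1) in inflamed against tolerized cells, with 179 and 174 without inflamed 1 and 2. It gave 107 (without activated 2) to 328 (without inflamed 3) in inflamed against activated cells, with 125 and 121 without inflamed 1 and 2. It gave 21 (without naive 2) to 49 (without inflamed 3) of opposite direction, with 23, 23 and 25 without naive 1, naive 3 and inflamed 1. The cause was not tested. In the 4 other comparisons not all 3 same-number pairs correlated over 0.1 (1 of 3 in inflamed against tolerized, 0 of 3 against naive cells). Across all groups 6 of 12 libraries correlated best with their own number. The block over all 12 libraries gave 8824, 9169, 0, 350, 228 and 9027 genes and 86 list calls. It added G2/M in tolerized against naive cells (0.0332) and ended gamma delta T in inflamed against activated (0.0886) and dendritic in inflamed against naive cells (0.051). Over named genes and settings 24631 results kept their call or lack of one, 231 gained a call and 758 lost it. In 0 results did the sign turn with a call in either fit. Sizes of change were not compared, and genes called in neither fit count among the 24631 whatever their sign. The planned tests for counts with dispersion models were not run as alternatives, because the unit had been recorded as other.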

Other observations

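Single libraries stood apart in several effector and stress genes. In tolerized replicate 3 the granzyme genes Gzmb and Gzma stood at 260.8 and 19.0 CPM, against 35.4 and 37.9 and against 0.684 and 0.692 CPM in replicates 1 and 2, and the integrin gene Itgax at 35.9 against 2.89 and 3.19 CPM. In naive replicates 1, 2 and 3 the immediate-early genes Fos and Jun stood at 4.13, 64.3 and 548.9 CPM and at 9.74, 202.7 and 944.1 CPM. The regulatory T cell gene Foxp3 stood between 31.8 and 49.9 CPM in all 12 libraries, while Cd4 fell in activated cells by 1.73 ± 0.23 on the log2 scale.

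Transcripts of other cells and tissues differed between libraries. Alb, the serum albumin gene of liver, stood at 30.01 CPM in activated replicate 3 and 15.2 CPM in inflamed replicate 1, and Serpina3k, another liver gene, at 5.12 CPM in activated replicate 3. Csf1r, the macrophage colony-stimulating factor receptor gene, stood at 156.1, 369.7 and 367.7 CPM in the naive libraries at 124.4 CPM in activated replicate 1, at 37.0 CPM in inflamed replicate 1 and at 0.621 to 29.7 CPM in the other 7 antigen-exposed libraries. The stromal genes Ogn and Ecm2 lie within the span of the centromere gene Cenpp (chromosome 13, 49464025 to 49652950), and all 3 varied together in the tolerized libraries, Ogn at 1.94, 7.99 and 8.97, Ecm2 at 2.74, 11.4 and 12.7 and Cenpp at 0.418, 1.67 and 2.74 CPM.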
